A study of Homo sapiens with 15 samples.

How the data were processed

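Messenger RNA was sequenced from 15 human cultures of self-renewing neuromesodermal progenitors (srNMPs), embryonic stem cells (ESCs) and cells differentiated from srNMPs. The labels give TruSeq Stranded mRNA libraries read on a NovaSeq instrument. Per the submitters' processing notes, Trimmomatic, HISAT2, HTSeq and Cufflinks were used with genome build hg18; their versions, settings and roles and the gene lengths behind the values are not stated. The deposited table lists FPKM (fragments per kilobase of transcript scaled to mapped fragments) for 17999 gene symbols. Its values were taken as listed. Genes are named by the symbols of the table, and no coordinates are given, since none are in the table and hg18 annotation was not used here. 1 column of values, headed H1, matched no sample and was not used.

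FPKM hold no read counts, so depth was estimated from the smallest values. Once libraries are scaled to each other, a gene's low FPKM values should be whole multiples of the value of 1 fragment. Its smallest value was taken as 1 fragment. Over 478 genes and 1970 values of up to 0.1 FPKM, 93.4% were whole multiples within 2%. The depth of each library relative to the mean of the libraries was 0.954 to 1.051 by this measure. With transcript lengths of a reference annotation for 355 genes, the H1 dorsal neuron library held about 35.7 M fragments (median over genes, quartiles 33.9 and 47.1). These are estimates, and no counting interval was computed from them. Summed FPKM ranged from 290306 to 421109, and the 10 most abundant genes took 5.65% to 11.92% of the sum.

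Libraries were placed in 9 groups by their labels. Of these, 6 groups held 1 H1 and 1 HUES9 library, and 3 groups held 1 HUES9 library. The replicates of a group are therefore its cell lines, and the labels do not say whether cultures were independent beyond that. Pairing comes from the cell line named in the labels. It was checked by correlating, across genes, the HUES9 minus H1 difference of each group with that of every other group; genes are not independent replicates, so no p is given.

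Genes with at least 1 FPKM in at least 1 library were kept, which left 14129. Values were log2-transformed after adding 1. limma 3.58.1 in R 4.3.3 fitted 1 mean per group and 1 term for the cell line (the replicate block), with a trend of variance on level, 5 residual degrees of freedom and 2.16 prior degrees of freedom. Each of 9 comparisons was a contrast of group means. Where a state had 2 groups (passages, inductions, neuron types or muscle days) their means were averaged. Tests were two-sided moderated tests, adjusted over all genes of a comparison by Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. The ESC library and both muscle libraries have no replicate, so they are assumed to vary like the other groups. They add nothing to the estimated spread. For a gene near 0 in the groups with both lines, the standard error and p therefore reflect mainly the spread of near-zero values. They do not measure how ESC or muscle cultures vary. Adding 1 FPKM shrinks the log2 changes of weakly expressed genes. No fold is given against a group listed at 0, since the fragments that a 0 allows are unknown.

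Lists of genes (31) were fixed before the data were examined, as were the comparisons, the tests, most alternatives and the rule for named genes. They cover pluripotency, neuromesodermal progenitor, WNT and FGF feedback targets, paraxial mesoderm and somite, neural progenitor, dorsal and ventral neural progenitor, dorsal and ventral interneuron, motor neuron, hedgehog targets, BMP targets, retinoic acid responsive, pan-neuronal, neurotransmitter, neural crest and peripheral glia, central glia, myogenic regulator, sarcomere, cardiac, fibroblast and smooth muscle, cartilage and tendon, endoderm, endothelial and blood, surface ectoderm, forebrain and midbrain, proliferation and cell stress genes, and HOX genes by paralog number (1 to 5, 6 to 9, 10 to 13). Some genes stand in more than 1 list. Each list with at least 3 tested members was tested against all other genes by camera of limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Over all comparisons 74 list tests, each chosen for the question of its comparison, are reported first, of which 40 were called with the preset correlation and 8 with an estimated one. The median, the mean and the test differed in sign for 14 of the 74, and 0 of these were called. Equal-total rescaling and quantile normalization reversed 0 of the 423 calls of list members.

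The rule named, for each list of a comparison, its first member and the called members with the largest changes whose higher group mean was at least 5 FPKM. It also named the 5 genes with the largest called change in each direction, changed the same way in both lines where both were present, at a mean of at least 5 FPKM and without an identifier as name. Other genes are said to be chosen after their values were seen. Some genes that the rule names are not reported here.

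Agreement of the lines is Pearson's r across genes between the log2 changes in H1 and in HUES9. A model with a separate change per line tested their difference in progenitors and in neurons. In it the 2 groups of a state stood as its 2 libraries per line, so differences between those groups entered the residual spread. Muscle at day 50 and day 40 was compared without a test; the median of each list was placed among the medians of 10000 random lists of the same size.

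Each result was recomputed with a pseudocount of 0.1, without the filter, with FPKM rescaled to equal totals (TPM scale), with quantile normalization, without the cell line term, with only the libraries of the contrast, with a minimum log2 change of 1, with muscle days as 1 group and without each library in turn. In HUES9 against H1 the line is the contrast, so the fit without the replicate block dropped the group means instead. It held all 15 libraries, so the HUES9-only ESC and muscle libraries mix line with state there. After the data were seen, the fits with the cell lines of the RASS libraries exchanged, the fits without both RASS libraries and the list tests at equal totals were added.

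Calling was tested on simulated data with this design and known changes. Changes were placed only in genes of higher mean level, with noise drawn independently for each gene. The shares recovered therefore do not cover weakly expressed genes. Of genes changed by 2 on the log2 scale, 71.1% were recovered for srNMPs against ESCs, 87.7% between passages, 81.7% between inductions, 91.2% between neuron types and 92.6% to 98.4% in the other comparisons simulated. Of genes changed by 1 (2-fold), these shares were 16.7%, 29.3%, 32.4%, 43.5% and 45.9% to 75.4%. In these simulations 1 to 13 unchanged genes were called. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.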

Results

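RNA was measured in srNMPs, progenitors that can give rise to spinal cord neurons and to skeletal muscle, and in their derivatives. The cells came from H1 and HUES9, both established human embryonic stem cell lines. The 15 libraries formed 9 groups. srNMPs were taken at passage 8 and at passage 25. Inductions of 7 days were labelled RABC and RASS, abbreviations that the labels leave unexplained. These 4 groups, the dorsal neurons and the ventral neurons each held 1 library of H1 (replicate 1) and 1 of HUES9 (replicate 2). The ESC group, muscle at day 40 and muscle at day 50 each held 1 HUES9 library and so have no replicates. Levels are given in FPKM as mean ± SD over libraries, and changes as log2(FPKM + 1) differences ± standard error, with adjusted p from limma.

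Estimated depth differed little between libraries, from 0.954 to 1.051 of their mean, and 10785 to 12102 genes reached 1 FPKM in a library. Spearman's rho across genes, which are not independent replicates, was 0.932 to 0.973 between the lines of a group (6 pairs). Libraries of different groups of the same state gave 0.886 to 0.982 (13 pairs), and libraries of different states 0.644 to 0.964 (86 pairs). The first 3 principal components held 35.2%, 31.6% and 10.1% of the variance.

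**Figure D1:**
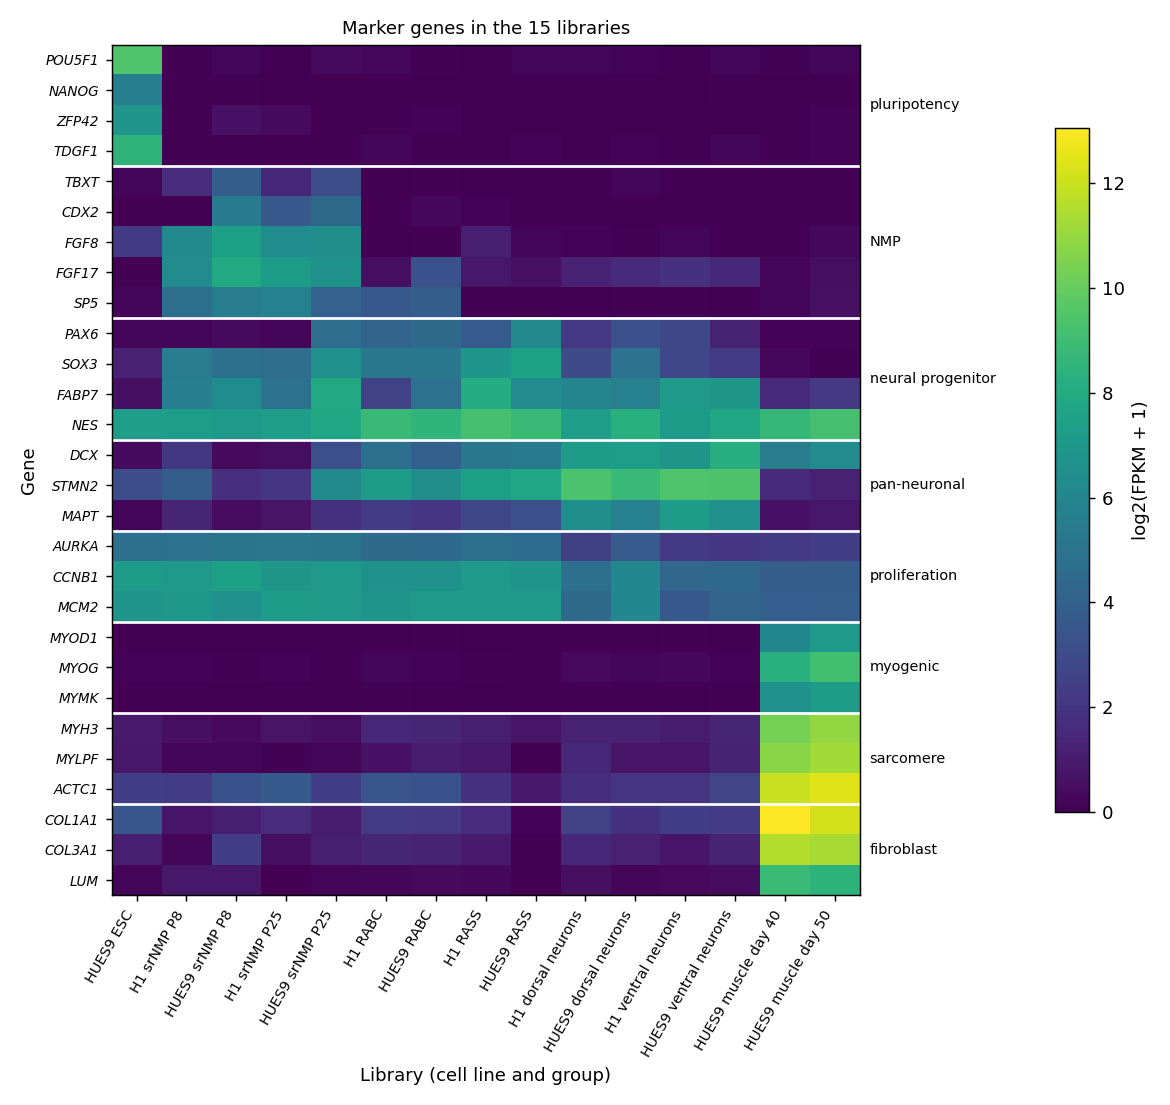
Heat map of 28 marker genes (vertical axis, grouped by list) in the 15 libraries (horizontal axis), coloured by log2(FPKM + 1). POU5F1 stood at 691 FPKM in the ESC library, STMN2 at 623 ± 116 in the 4 neuron libraries and MYOG at 426 ± 161 in the 2 muscle libraries.

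srNMPs of both lines were compared with HUES9 ESCs to see what separates them from pluripotent cells. Most pluripotency genes were lower in srNMPs. POU5F1, a core transcription factor of pluripotency, stood at 0.144 ± 0.137 FPKM (SD, n = 4) against 691 in the ESC library (log2 change -9.20 ± 0.18, adjusted p = 1.21e-07). NANOG, another core factor, fell from 47.0 to 0.0307 ± 0.0327 FPKM (log2 change -5.54 ± 0.09, adjusted p = 8.2e-08). The single ESC library adds nothing to the standard errors and p of this comparison, which do not measure variation between ESC cultures. ZFP42 (-6.52 ± 0.24) and PRDM14 (-5.97 ± 0.09) fell as well. The DNA methyltransferase gene DNMT3B fell from 549 but stayed at 37.7 ± 11.7 FPKM (-3.94 ± 0.22). TDGF1, a NODAL co-receptor, was listed at 0 in all 4 srNMP libraries and at 362 FPKM in the ESC library (adjusted p = 8.2e-08). Of 14 pluripotency genes tested, 13 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 1.98e-21, and adjusted p = 0.00407 with an estimated correlation). The exception was LIN28A, an RNA-binding protein of early progenitors, at 276 ± 43.3 against 477 FPKM (adjusted p = 0.66). Other large decreases were those of CDH1, which encodes E-cadherin (log2 change -6.59 ± 0.49, adjusted p = 0.000183), the tight junction gene CLDN6 (-8.75 ± 0.28) and EPHA1 (-6.57 ± 0.12).

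HOX genes, which set position along the body axis, were high in srNMPs. HOXB9 reached 309 ± 88.5 FPKM against 0.609 in the ESC library (log2 change 7.35 ± 0.43, adjusted p = 5.12e-05). HOXB7 reached 93.0 ± 44.3 against 0.0444 (log2 change 6.44 ± 0.48, adjusted p = 0.000183) and HOXA9 49.5 ± 29.5 against 0.0293 (log2 change 5.70 ± 1.04, adjusted p = 0.0118). Among paralogs 6 to 9, 7 of 12 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.51e-06, but adjusted p = 0.222 with an estimated correlation). Among paralogs 1 to 5, 13 of 15 rose, 14 adjusted over the list alone (camera adjusted p = 3.11e-10, but adjusted p = 0.222 with an estimated correlation). HOXB3 rose by 4.95 ± 0.32. HOXB4 was listed at 0 in the ESC library and stood at 26.1 ± 11.97 FPKM in srNMPs (adjusted p = 0.00097). HOXA6, also listed at 0 there, had 3.16 ± 2.17 FPKM (adjusted p = 0.196). In the posterior paralogs 10 to 13, 0 of 10 rose and HOXB13 fell by 1.52, 1 gene also adjusted over the list alone (camera adjusted p = 0.795). HOXA10 and HOXC10 had 1.85 ± 1.82 and 5.82 ± 6.88 FPKM in srNMPs (adjusted p = 0.437 and 0.406). The ESC library is HUES9, and in the HUES9 srNMPs alone HOXA10 stood at 3.38 (passage 8) and 3.43 (passage 25) against 0.0119 and HOXC10 at 14.6 and 8.01 against 0.123 FPKM.

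Signalling genes of the tail bud were raised in part. FGF17 (140.4 ± 72.9 FPKM against 0.0668, log2 change 7.23 ± 0.91, adjusted p = 0.00253) and FGF8 (log2 change 4.41 ± 0.50, adjusted p = 0.00151), ligands of the tail bud, rose together with the WNT target SP5 (4.79 ± 0.59). TBXT, the mesodermal partner gene of the neuromesodermal state, rose to 6.20 ± 5.45 FPKM (log2 change 2.62 ± 0.67, adjusted p = 0.0394). Its neural partner SOX2 stood at 171 ± 28.8 against 113 (adjusted p = 0.14). CDX2, a trunk regulator listed at 0 in the ESC library, had 18.1 ± 16.5 FPKM (adjusted p = 0.115). NKX1-2 had 4.53 ± 4.76 against 49.6 (adjusted p = 0.0582). Of 16 neuromesodermal genes 6 rose, among them WNT5A (2.84 ± 0.78), and CYP26A1, a retinoic acid hydroxylase, fell. Adjusted over the list alone 6 rose and 2 fell (camera adjusted p = 0.156). WNT and FGF feedback targets had 6 of 19 genes up and 1 down, and 9 up and 1 down adjusted over the list alone (camera adjusted p = 0.0121, but adjusted p = 0.448 with an estimated correlation). LEF1 (log2 change 4.64 ± 0.48, adjusted p = 0.000941), LGR5 (3.59 ± 0.83) and AXIN2 (1.65 ± 0.38), all WNT-induced, rose, and the FGF antagonist SPRY4 fell (-2.29 ± 0.56).

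Of 18 neural progenitor genes 6 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00111, but adjusted p = 0.448 with an estimated correlation). They include the radial glia gene FABP7 (log2 change 5.98 ± 1.23, adjusted p = 0.0186), SOX3 (4.45 ± 0.80) and the neurogenic factor NEUROG2 (2.93 ± 0.65). PAX6 stood at 6.30 ± 12.2 against 0.136 FPKM (adjusted p = 0.459). PRTG, a receptor of early neural and somitic tissue, rose by 5.93 ± 0.81. Of 15 paraxial mesoderm and somite genes limma called 0 (3 at an unadjusted p under 0.05), with 0 adjusted over the list alone (camera adjusted p = 0.908). The NOTCH ligand gene DLL3 had 7.57 ± 4.31 against 1.07 FPKM (adjusted p = 0.103). Only 2 endoderm genes were tested, too few for a list test. CXCR4, a chemokine receptor, rose (4.42 ± 0.74) and EPCAM, also an epithelial gene, fell (-5.84 ± 0.43). In all, 2354 of 14129 genes were called, 1233 higher and 1121 lower. Without srNMP_P25 replicate 2 (HUES9) 1503 were called (700 and 803), and with only the 5 libraries of this contrast 365 (22 and 343, 6.03% higher). More genes were lower than higher also with quantile normalization (957 and 1166) and without the filter (1160 and 1530). The calls of TBXT, WNT5A and LGR5 ended without the cell line term, those of WNT5A and AXIN2 with quantile normalization, and that of SPRY4 under both scalings and the smaller pseudocount.

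**Figure D2:**
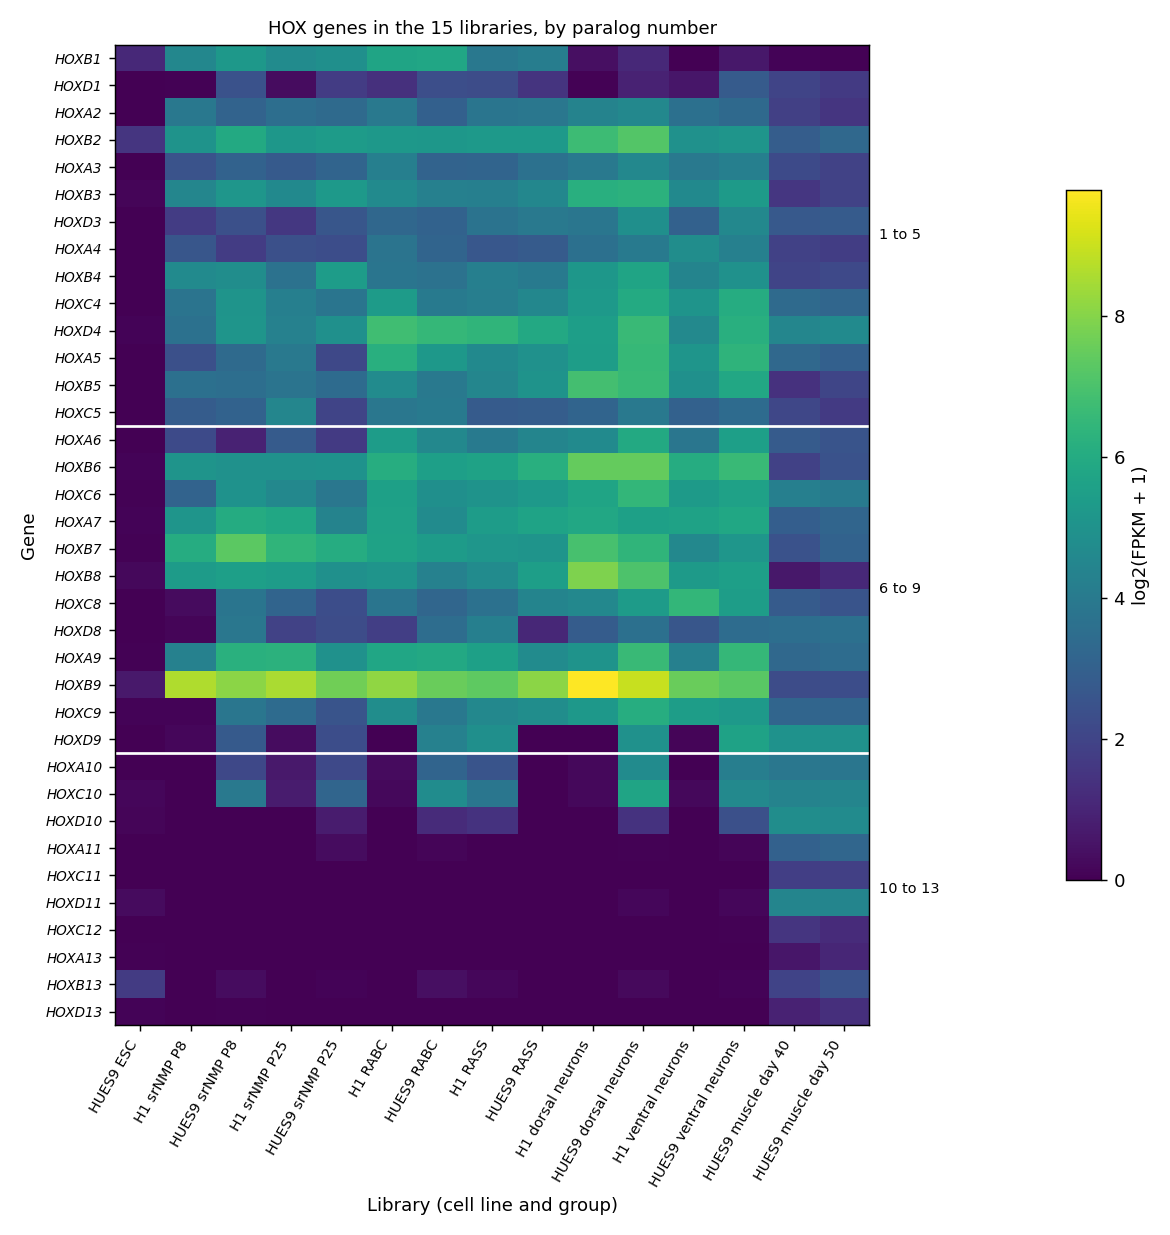
Heat map of 36 HOX genes (vertical axis, by paralog number) in the 15 libraries (horizontal axis), coloured by log2(FPKM + 1). HOXB9 stood at 0.609 FPKM in the ESC library and at 309 ± 88.5 in the 4 srNMP libraries.

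Passage 25 was compared with passage 8 to see whether continued culture changed the srNMPs. Neuromesodermal genes moved by a median log2 change of 0.341 in H1 and -0.383 in HUES9. TBXT had 4.63 ± 3.90 FPKM at passage 25 (SD, n = 2) and 7.77 ± 8.01 at passage 8, CDX2 16.6 ± 7.29 and 19.5 ± 27.6, SP8 15.5 ± 7.60 and 8.19 ± 9.68, and AXIN2 27.5 ± 9.03 and 23.9 ± 1.40. HOXA6 had 4.06 ± 2.68 and 2.26 ± 1.93 FPKM, HOXC9 7.32 ± 3.56 and 6.62 ± 9.28, and HOXA10 2.002 ± 2.03 and 1.70 ± 2.39. CDX2 went from 0.00615 at passage 8 to 11.5 at passage 25 in H1 and from 39.0 to 21.8 in HUES9, and HOXC9 from 0.0565 to 9.84 and from 13.2 to 4.80. The proliferation gene MKI67 had 53.2 ± 16.6 and 39.9 ± 33.5, and the somite clock gene LFNG 13.03 ± 0.717 and 7.96 ± 1.42. NKX6-1 and PAX6, genes of spinal cord progenitors, had 11.5 ± 14.9 and 12.3 ± 17.2 FPKM at passage 25 against 0.123 ± 0.0159 and 0.251 ± 0.103. The high values were those of the HUES9 library alone (22.0 and 24.5 FPKM). limma called 0 genes between the passages (smallest adjusted p = 1), with 255 at an unadjusted p under 0.05. On simulated data the test recovered 29.3% of changes of 1 and 87.7% of changes of 2 on the log2 scale. Those changes were placed only in genes of higher mean level, so the shares do not cover weakly expressed genes. The 8 lists set for this comparison, for neuromesodermal, WNT and FGF, HOX (3 lists), neural progenitor, paraxial mesoderm and proliferation genes, had 0 called members (1 WNT and FGF and 1 neural progenitor gene at an unadjusted p under 0.05) and camera adjusted p from 0.319 (neural progenitor) to 0.935 (neuromesodermal). The neural crest list, not set for this comparison, was lower at passage 25 (camera adjusted p = 2.15e-05, but adjusted p = 0.493 with an estimated correlation), with 0 of 12 genes called, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05. Its mean log2 level was 2.22 in HUES9 at passage 8 and 0.990 to 1.24 in the other 3 srNMP libraries. Adjusted over the list alone, 1 gene of the 8 set lists was called, RNF43, a WNT feedback gene (1.14 ± 0.19). Of the other lists, fibroblast and smooth muscle had 1 higher and 1 lower (camera adjusted p = 0.851). Leaving out 1 library gave 1 to 5 calls, and these genes were named after their values were seen. They were FOXL2NB without srNMP_P25 replicate 1 (1 gene), CHI3L1, CPA6 and PECAM1 without srNMP_P25 replicate 2 (3 genes), CD36, GJB1, GNAT3 and PRSS56 without srNMP_P8 replicate 1 (4 genes), and CDX2, L1TD1, PLAC1, TARP and URAD without srNMP_P8 replicate 2 (5 genes).

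The 7-day inductions RABC and RASS, pooled as progenitors, were compared with srNMPs to follow the first step out of self-renewal. Tail bud signals fell. FGF8 dropped from 102 ± 46.2 to 0.336 ± 0.531 FPKM (SD, n = 4 each; log2 change -6.26 ± 0.30, adjusted p = 0.00178), FGF17 from 140.4 ± 72.9 to 2.62 ± 4.12 (log2 change -5.71 ± 0.56, adjusted p = 0.00762). HES3, a HES-family repressor of progenitors, fell from 24.6 ± 16.1 to 0.545 ± 0.810 (log2 change -4.00 ± 0.35, adjusted p = 0.00504). TBXT (-2.50 ± 0.41) and SP5 (-3.15 ± 0.36) fell too. SOX2 stood at 197 ± 69.6 against 171 ± 28.8 (adjusted p = 0.58) and CDX2 at 0.0826 ± 0.107 against 18.1 ± 16.5 (adjusted p = 0.0922). Of 16 neuromesodermal genes 6 fell and 0 rose. Adjusted over the list alone 9 fell and 1 rose (camera adjusted p = 0.000242, but adjusted p = 0.419 with an estimated correlation). Of 19 WNT and FGF feedback targets 8 fell and 0 rose, 9 and 0 adjusted over the list alone (camera adjusted p = 3.02e-07, but adjusted p = 0.301 with an estimated correlation). The FGF antagonists SPRY1 (log2 change -3.35 ± 0.50, adjusted p = 0.0262), SPRY2 (-3.33 ± 0.47) and DUSP6 (-3.02 ± 0.56) were among them. AXIN2 stood at 25.9 ± 20.4 against 25.7 ± 5.67 (adjusted p = 0.432).

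Some neural genes rose. NEUROG2 rose from 6.92 ± 4.96 to 65.3 ± 13.3 FPKM (log2 change 3.31 ± 0.40, adjusted p = 0.0147) and NES, the neural stem cell filament, from 165 ± 39.8 to 467 ± 84.2 (log2 change 1.51 ± 0.25, adjusted p = 0.0326). These were the 2 of 18 neural progenitor genes that rose, against 8 adjusted over the list alone (camera adjusted p = 0.00057, but adjusted p = 0.455 with an estimated correlation). PAX6 stood at 30.3 ± 26.0 against 6.30 ± 12.2 (adjusted p = 0.0861). Of 24 pan-neuronal genes 8 rose and 0 fell, 16 and 1 adjusted over the list alone (camera adjusted p = 3.02e-07, but adjusted p = 0.455 with an estimated correlation). DCX, a microtubule protein of young neurons (log2 change 3.29 ± 0.66, adjusted p = 0.0475), the RNA-binding protein gene ELAVL3 (3.12 ± 0.60) and MAP2 (1.98 ± 0.32) were among them. TUBB3 had 436 ± 129 against 212 ± 69.5 FPKM (adjusted p = 0.0727) and STMN2 153 ± 53.0 against 22.8 ± 33.2 (adjusted p = 0.0665). Of 9 retinoic acid responsive genes 2 rose, among them the receptor gene RARB (2.65 ± 0.51), and the retinol importer gene STRA6 fell (-2.42 ± 0.40), with 3 up and 1 down adjusted over the list alone (camera adjusted p = 0.72).

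Among HOX paralogs 6 to 9 only HOXA6 rose (log2 change 2.72 ± 0.54, adjusted p = 0.0475; 2 up and 1 down adjusted over the list alone; camera adjusted p = 0.448), with HOXC9 at 22.7 ± 6.04 against 6.97 ± 5.75 FPKM (adjusted p = 0.152). Paralogs 10 to 13 had 0 of 10 called in limma and 0 at an unadjusted p under 0.05, with 0 adjusted over the list alone (camera adjusted p = 0.99), and HOXA10 stood at 3.23 ± 3.80 against 1.85 ± 1.82 (adjusted p = 0.926). Proliferation genes had 0 of 18 called and 0 at an unadjusted p under 0.05, with 0 adjusted over the list alone (camera adjusted p = 0.99). MKI67 stood at 90.0 ± 14.2 against 46.6 ± 22.9 (adjusted p = 0.23). In the neural crest list NGFR rose (2.41 ± 0.43) and SNAI2 fell (-1.79 ± 0.36), 1 up and 2 down adjusted over the list alone (camera adjusted p = 0.118, and 0.00605 at equal totals). The crest factor SOX10 had 0.00490 ± 0.00979 FPKM in progenitors, and in srNMPs 9.89 in HUES9 at passage 8 and 0 to 0.241 in the other 3 libraries. The largest increases were FGFR3, an FGF receptor of the ventricular zone (log2 change 4.38 ± 0.39, adjusted p = 0.00504), LAMP5 (4.23 ± 0.50), RHBDL3 (4.15 ± 0.71), the guidance receptor EPHA3 (3.96 ± 0.68) and RARRES2 (3.89 ± 0.67). Besides FGF8 and FGF17, IFITM1 (-5.22 ± 0.62) and C3orf52 (-4.38 ± 0.52) were among the largest decreases.

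In this comparison of progenitors with srNMPs 484 genes were called, 245 higher and 239 lower (50.6% higher). All 484 had the same sign in both lines as labelled, which calling with 1 library per line and group favours. At equal totals 62.9% were higher (372 and 219), and the median change of all genes was 0.18 against 0.02 as listed. The share higher was 25.3% without srNMP_P8 replicate 2 (25 and 74) and 45.2% with quantile normalization (232 and 281). The count depended on single libraries. It was 45 without RABC_7D replicate 1, 63 without srNMP_P25 replicate 1, 99 without srNMP_P8 replicate 2, 119 without RASS_7D replicate 2, 284 without RASS_7D replicate 1 and 2281 without srNMP_P8 replicate 1. It was 0 with only these 8 libraries and 1 mean for each of the 4 groups, 772 without the replicate block, 191 without the filter, 25 without both RASS libraries and 875 with the lines of the RASS libraries exchanged. The calls of DCX (smaller pseudocount, equal totals) and HOXA6 (quantile normalization) ended under those settings.

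RASS was compared with RABC to see how the inductions differ. Some ventral genes and targets of hedgehog signalling were higher in RASS, and some dorsal genes lower. OLIG2, the factor of motor neuron progenitors, was listed at 0 in both RABC libraries and had 117 ± 92.8 FPKM in RASS (SD, n = 2; adjusted p = 0.0253). NKX6-2, a ventral progenitor factor, rose from 0.0226 ± 0.0320 to 8.12 ± 2.22 (log2 change 3.14 ± 0.24, adjusted p = 0.00563). NKX6-1 had 114 ± 63.3 against 0.299 ± 0.411 (adjusted p = 0.055) and NKX2-2 18.5 ± 8.62 against 0.00584 ± 0.00826 (adjusted p = 0.251). OLIG2 and NKX6-2 were the 2 of 8 ventral progenitor genes that rose, 5 adjusted over the list alone (camera adjusted p = 3.03e-06, but adjusted p = 0.424 with an estimated correlation). The hedgehog receptor PTCH1 rose to 242 ± 9.92 FPKM (log2 change 3.37 ± 0.50, adjusted p = 0.0498), as did the antagonist HHIP (log2 change 3.79 ± 0.32, adjusted p = 0.00687) and the effector GLI1 (log2 change 3.11 ± 0.26, adjusted p = 0.00687). They were among 4 of 7 called hedgehog targets, 5 adjusted over the list alone, with 0 down (camera adjusted p = 2.37e-10, and adjusted p = 0.0323 with an estimated correlation).

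Of 15 dorsal progenitor genes the dorsal factors ZIC1 (103 ± 28.6 to 0.422 ± 0.338 FPKM, log2 change -6.18 ± 0.45, adjusted p = 0.00508), ZIC2 (log2 change -4.89 ± 0.38, adjusted p = 0.00563) and ZIC5 (log2 change -4.23 ± 0.34, adjusted p = 0.0064) fell. Adjusted over the list alone 11 fell and 1 rose (camera adjusted p = 9.36e-17, and adjusted p = 0.0323 with an estimated correlation). PAX3 had 0.0900 ± 0.118 against 35.8 ± 19.95 (adjusted p = 0.0739), MSX1 0.343 ± 0.0731 against 81.7 ± 62.9 (adjusted p = 0.094) and OLIG3 0.00646 ± 0.00913 against 102 ± 111 (adjusted p = 0.16). BMP targets had 0 of 12 called in limma (3 at an unadjusted p under 0.05, and 3 lower adjusted over the list alone; camera adjusted p = 0.0015, but adjusted p = 0.441 with an estimated correlation). ID1, induced by BMP, stood at 87.8 ± 83.5 against 64.6 ± 62.1 FPKM and ID3 at 18.7 ± 16.5 against 145 ± 94.5. In the neural crest list TFAP2B fell (log2 change -2.96 ± 0.43, adjusted p = 0.0476; 1 of 12, also adjusted over the list alone; camera adjusted p = 0.576). SOX10 was listed at 0 in RASS and at 0.00979 ± 0.0139 FPKM in RABC. Motor neuron genes had 0 of 15 called (2 at an unadjusted p under 0.05), 1 up and 1 down adjusted over the list alone (camera adjusted p = 0.152), with MNX1 at 3.35 ± 4.64 against 0.102 ± 0.0678.

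Other large increases in RASS were DBH, an enzyme of noradrenaline synthesis (log2 change 5.32 ± 0.55, adjusted p = 0.014), the ligand FGF19 (4.71 ± 0.64) and ELF4 (4.03 ± 0.24). The hedgehog co-factor SCUBE2 (-5.21 ± 0.68) and ISM1 (-4.55 ± 0.54) fell. Between RASS and RABC 73 genes were called, 45 higher and 28 lower, against 1206 at an unadjusted p under 0.05. All 73 had the same sign in both lines as labelled, which calling with 1 library per line and group favours. The count was 8 without RABC_7D replicate 1 (4 and 4), 32 without RABC_7D replicate 2 (10 higher and 22 lower, 31.2% higher), 48 without the filter, 0 with only these 4 libraries and 113 with the lines of the RASS libraries exchanged, of which 70 were among the 73. The calls of PTCH1 (smaller pseudocount, equal totals, no replicate block), SCUBE2 (smaller pseudocount, equal totals), HHIP and FGF19 (smaller pseudocount) and TFAP2B (no replicate block) ended under those settings. At equal totals the median change of all genes was 0.13 against 0.03 as listed.

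Neurons, dorsal and ventral together, were compared with srNMPs to describe neuronal differentiation. Neuronal genes rose widely. STMN2, a growth cone protein, rose from 22.8 ± 33.2 to 623 ± 116 FPKM (SD, n = 4 each; log2 change 5.79 ± 0.87, adjusted p = 0.00176), DCX from 3.05 ± 3.74 to 174 ± 74.2 (log2 change 5.84 ± 0.66, adjusted p = 0.00059). MAPT, which encodes tau, rose from 1.29 ± 1.01 to 94.5 ± 37.0 (log2 change 5.40 ± 0.35, adjusted p = 0.000126). TUBB3, a neuronal tubulin gene, rose as well (1.45 ± 0.26). Of 24 pan-neuronal genes 21 rose and 0 fell, 22 and 1 adjusted over the list alone (camera adjusted p = 7.53e-09, but adjusted p = 0.477 with an estimated correlation). Of 13 neurotransmitter genes 10 rose and 0 fell, 10 and 1 adjusted over the list alone (camera adjusted p = 0.00802, but adjusted p = 0.501 with an estimated correlation, and 0.0527 at equal totals). They include the vesicular glutamate transporter SLC17A6 (0.0712 ± 0.0798 to 16.4 ± 6.96 FPKM, log2 change 3.94 ± 0.26, adjusted p = 0.000128), the glycine transporter SLC6A5 (2.95 ± 0.53) and the neuropeptide gene SST (log2 change 5.16 ± 0.76, adjusted p = 0.00158). GAD1, a GABA synthesis enzyme, had 14.98 ± 16.1 against 30.4 ± 15.5 (adjusted p = 0.0714). The largest increases were EEF1A2 (7.16 ± 0.37), NSG2 (6.75 ± 0.50), LAMP5 (6.30 ± 0.50) and PCSK1N (6.02 ± 0.28), besides DCX.

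Progenitor and cell cycle genes fell in the neurons. FGF8 (log2 change -6.49 ± 0.30, adjusted p = 5.34e-05), FGF17 (-5.46 ± 0.56), SP5 (-4.98 ± 0.36) and TBXT (-2.47 ± 0.41) were among 10 of 16 neuromesodermal genes that fell, 11 adjusted over the list alone, with 0 up (camera adjusted p = 0.00109, but adjusted p = 0.477 with an estimated correlation). The largest decreases were LIN28A (276 ± 43.3 to 0.418 ± 0.377 FPKM, log2 change -7.63 ± 0.61, adjusted p = 0.000208), C3orf52 (-5.43 ± 0.52) and PRTG (-5.32 ± 0.50), besides FGF8 and FGF17. Of 18 proliferation genes 17 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 7.98e-08, but adjusted p = 0.628 with an estimated correlation). The mean log2 level of this list was 5.57 in HUES9 dorsal neurons, 3.49 to 4.10 in the other 3 neuron libraries and 6.03 to 6.23 in srNMPs, and MKI67 stood at 67.2 FPKM in HUES9 dorsal neurons. The mitotic kinase AURKA (log2 change -2.42 ± 0.25, adjusted p = 0.00045) and the replication licensing genes MCM2 (-2.37 ± 0.31) and MCM3 (-2.36 ± 0.25) fell. MKI67 stood at 28.6 ± 26.2 against 46.6 ± 22.9 (adjusted p = 0.177).

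Of 12 central glia genes 8 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0274, but adjusted p = 0.477 with an estimated correlation, and 0.0762 at equal totals). The gliogenic factors SOX9 (2.45 ± 2.85 to 54.3 ± 10.3 FPKM, log2 change 4.29 ± 0.46, adjusted p = 0.000518) and NFIA (3.28 ± 0.24) and HOPX (3.52 ± 0.52) rose. GFAP, the astrocyte filament, rose to a mean of 6.32 ± 6.29 FPKM (2.20 ± 0.62), but not in every neuron library. It stood at 0.0267 in HUES9 dorsal neurons, 2.19 to 13.5 in the other neuron libraries and 0.0171 to 0.0431 in srNMPs. The gap junction gene GJA1 fell (-2.62 ± 0.49). In the neural crest list 2 of 12 rose, among them NGFR (2.81 ± 0.43), and SNAI2 and ERBB3 fell (2 genes), with 1 up and 2 down adjusted over the list alone (camera adjusted p = 0.947), with SOX10 at 1.63 ± 2.21 FPKM in neurons and, besides the HUES9 library of passage 8 (9.89), 0 to 0.241 in srNMPs. In the fibroblast and smooth muscle list 3 of 12 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.947). COL1A1 rose to 4.04 ± 0.928 FPKM (1.18 ± 0.28), and the contractile genes ACTA2 (-2.07 ± 0.56) and TAGLN (-2.02 ± 0.46) fell. Among HOX paralogs 6 to 9, HOXA6 (3.10 ± 0.54), HOXC8 (3.07 ± 0.72) and HOXC9 (3.03 ± 0.73) were among 6 of 12 that rose, with 0 down, also adjusted over the list alone (camera adjusted p = 0.153, and 0.0259 with quantile normalization). In paralogs 10 to 13, limma called 0 of 10 (0 at an unadjusted p under 0.05), with 0 adjusted over the list alone (camera adjusted p = 0.947), with HOXA10 at 10.7 ± 12.7 against 1.85 ± 1.82. These means average unlike lines. In HUES9 HOXA10 stood at 25.5 (dorsal) and 17.1 FPKM (ventral) against 3.38 (passage 8) and 3.43 (passage 25). HOXC10 stood at 51.6 and 23.2 against 14.6 and 8.01 there. Both were at 0 to 0.661 in H1 neurons and srNMPs. The change within HUES9 was not tested. In neurons against srNMPs 7355 genes were called, 4076 higher and 3279 lower (55.4% higher), all with the same sign in both lines, and 3481 of them changed at least 2-fold. The share higher was 71.9% at equal totals (5412 and 2120) and 44.8% with quantile normalization (3238 and 3991). The median change of all genes was 0.35 at equal totals against 0.05 as listed.

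Ventral neurons were compared with dorsal neurons to see which spinal cord types each protocol held. Most dorsal interneuron and some dorsal progenitor genes were lower and some motor neuron genes higher in ventral neurons. LBX1, a factor of dorsal interneurons, had 0.554 ± 0.735 FPKM in ventral and 77.4 ± 10.1 in dorsal neurons (SD, n = 2; log2 change -5.74 ± 0.88, adjusted p = 0.0254). POU4F1, a sensory interneuron factor, had 0.309 ± 0.128 and 38.7 ± 12.5 (log2 change -4.89 ± 0.88, adjusted p = 0.0435), and LMX1B 0.338 ± 0.0670 and 29.8 ± 14.0 (log2 change -4.45 ± 0.45, adjusted p = 0.00567). TLX3 (-4.01 ± 0.54), which favours glutamatergic fate, and GBX1 (-3.59 ± 0.21) were also among 8 of 11 dorsal interneuron genes that were lower, with 0 higher, also adjusted over the list alone (camera adjusted p = 5.02e-11, but adjusted p = 0.133 with an estimated correlation). The vesicular acetylcholine transporter gene SLC18A3 had 22.6 ± 3.57 FPKM in ventral and 0.222 ± 0.129 in dorsal neurons (log2 change 4.27 ± 0.23, adjusted p = 0.000581). CHAT, which makes acetylcholine, had 7.83 ± 0.291 and 0.0541 ± 0.0471 (log2 change 3.07 ± 0.19, adjusted p = 0.00087). LHX3, a motor neuron factor (log2 change 3.67 ± 0.32, adjusted p = 0.00281), and SLC5A7, a choline importer (3.71 ± 0.51), completed 4 of 15 motor neuron genes higher, 9 and 1 lower adjusted over the list alone (camera adjusted p = 2.52e-07, but adjusted p = 0.301 with an estimated correlation). MNX1 stood at 20.1 ± 14.0 against 0.131 ± 0.186 (adjusted p = 0.0953).

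ZIC1 was at 0.113 ± 0.0180 FPKM in ventral and 168 ± 118 in dorsal neurons (log2 change -7.04 ± 0.45, adjusted p = 0.000952). PAX3 was lower (log2 change -5.46 ± 0.85, adjusted p = 0.0262), as was PAX7 (-4.24 ± 0.74). GSX2 was listed at 0 in ventral and at 14.0 ± 2.02 in dorsal neurons (adjusted p = 0.00014). Of 15 dorsal progenitor genes 6 were lower, 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.19e-06, but adjusted p = 0.263 with an estimated correlation). OLIG3 stood at 3.06 (H1) and 55.9 FPKM (HUES9) in ventral against 0.132 and 0.0131 in dorsal neurons. Of 18 proliferation genes limma called 0, with 16 lower adjusted over the list alone (16 at an unadjusted p under 0.05; camera adjusted p = 1.32e-11, but adjusted p = 0.386 with an estimated correlation). Their mean log2 level was 5.57 in HUES9 and 4.10 in H1 dorsal neurons, with MKI67 at 67.2 and 22.2 FPKM. NKX6-2 was the 1 of 8 ventral progenitor genes called higher (log2 change 2.77 ± 0.24, adjusted p = 0.00281), 5 adjusted over the list alone (camera adjusted p = 2.71e-05, but adjusted p = 0.386 with an estimated correlation). NKX6-1 stood at 43.8 ± 35.6 against 0.0124 ± 0.00577 (adjusted p = 0.0524) and NKX2-2 at 38.4 ± 49.98 against 0.0359 ± 0.0337 (adjusted p = 0.13). GATA3, a V2b interneuron factor, was the 1 of 9 ventral interneuron genes called higher (log2 change 2.22 ± 0.32, adjusted p = 0.0223), 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0245, but adjusted p = 0.386 with an estimated correlation). EN1 stood at 7.95 ± 6.86 against 5.76 ± 7.28 (adjusted p = 0.834). SOX14 and SIM1 were listed at 0 in dorsal and at 14.8 ± 17.4 and 2.58 ± 3.18 in ventral neurons (adjusted p = 0.0953 and 0.212).

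Of 13 neurotransmitter genes CHAT and SLC18A3 were higher and the GABA synthesis gene GAD2 was lower (log2 change -3.44 ± 0.40, adjusted p = 0.00972). Adjusted over the list alone 5 were higher and 5 lower (camera adjusted p = 0.789). SLC17A6 had 18.8 ± 9.74 and 13.9 ± 5.14 FPKM and SST 213 ± 164 and 21.8 ± 26.0 (adjusted p = 0.728 and 0.146). TFAP2B (log2 change -5.72 ± 0.43, adjusted p = 0.00164) and TFAP2A (-4.88 ± 0.82), which also mark dorsal interneurons, were the 2 of 12 neural crest genes lower in ventral neurons, also adjusted over the list alone (camera adjusted p = 0.916), with SOX10 at 3.04 ± 2.57 against 0.214 ± 0.147. Central glia genes had 0 of 12 called in limma (1 at an unadjusted p under 0.05), 1 higher adjusted over the list alone (camera adjusted p = 0.313), with GFAP at 7.84 ± 7.99 against 4.79 ± 6.74. PDGFRB, a pericyte receptor, was the 1 of 12 fibroblast and smooth muscle genes higher (2.31 ± 0.20), also adjusted over the list alone (camera adjusted p = 0.481), with ACTA2 at 4.17 ± 4.35 against 4.59 ± 0.751. UTS2, a peptide hormone gene of cholinergic neurons, was listed at 0 in dorsal and at 67.6 ± 30.7 in ventral neurons (adjusted p = 0.000145). TIMP3 (4.46 ± 0.34), the guidance cue SLIT3 (4.43 ± 0.51) and SPARCL1 (4.29 ± 0.66) were higher and PAX8 lower (-5.40 ± 0.63). Between ventral and dorsal neurons 288 genes were called, 207 higher and 81 lower (71.9% higher), all with the same sign in both lines. The count was 137 without dorsal_neurons replicate 2 (64 higher and 73 lower), 356 without dorsal_neurons replicate 1 (157 and 199) and 0 with only these 4 libraries. With quantile normalization 56.6% were higher (176 and 135). With the smaller pseudocount the calls of LBX1, POU4F1, TLX3, GATA3, SLC5A7, GAD2 and TFAP2A ended, and at equal totals that of POU4F1.

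**Figure D3:**
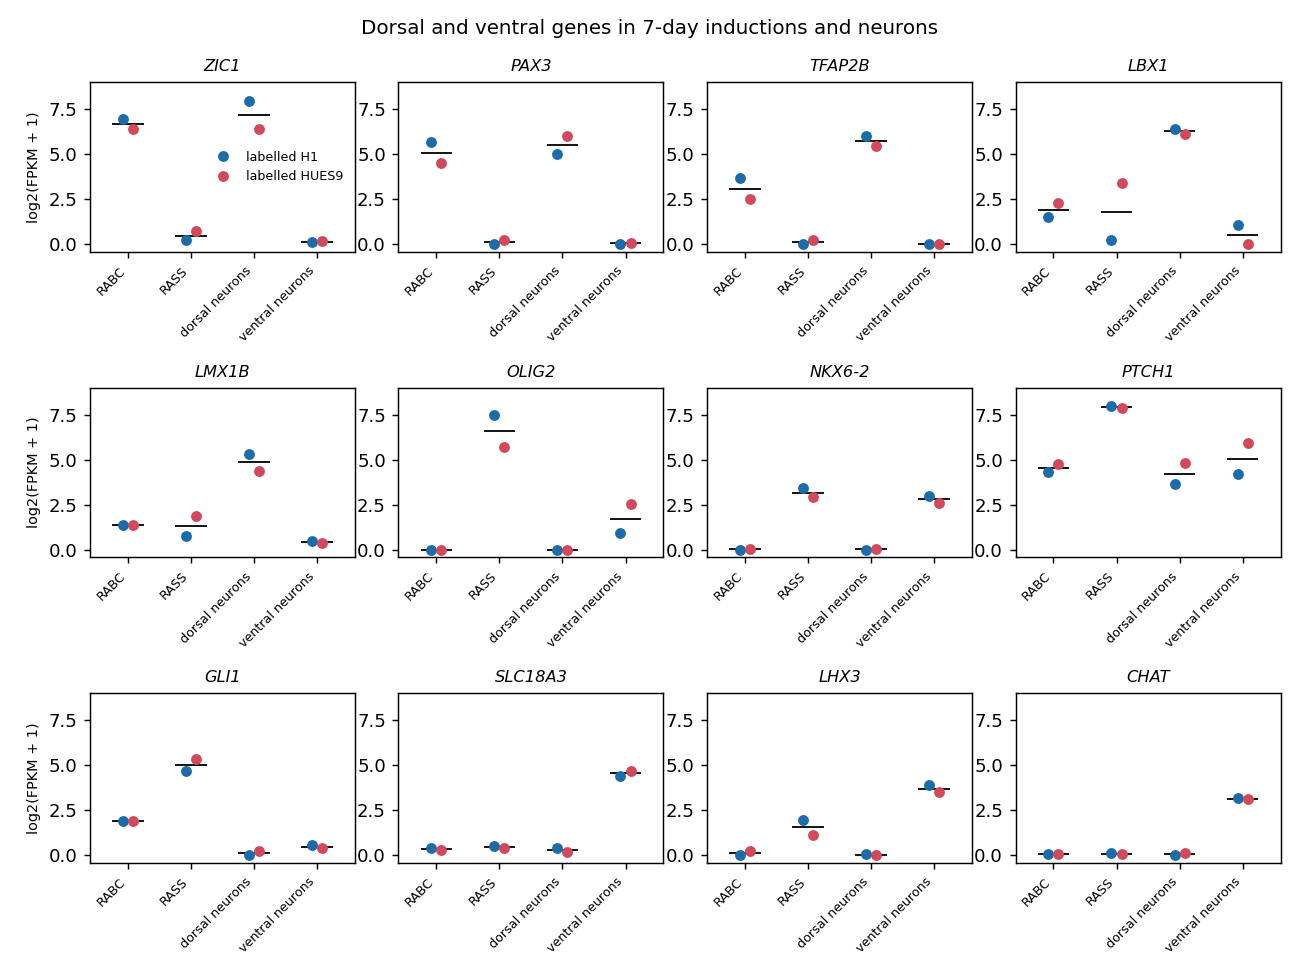
log2(FPKM + 1) of 12 dorsal, ventral, hedgehog and cholinergic genes (vertical axes) in the 7-day inductions and neurons (horizontal axes); points are libraries coloured by labelled line and bars are group means. ZIC1 stood at 103 ± 28.6 FPKM in RABC and 168 ± 118 in dorsal neurons, against 0.422 ± 0.338 in RASS and 0.113 ± 0.0180 in ventral neurons.

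Muscle at day 40 and day 50 was compared with srNMPs to describe muscle differentiation. Genes of muscle regulation and contraction reached high levels. MYOG, the factor of myoblast differentiation, had 426 ± 161 FPKM (SD, n = 2 muscle libraries, 1 per day) against 0.0605 ± 0.0412 in srNMPs (n = 4; log2 change 8.64 ± 0.11, adjusted p = 2.38e-08). MYOD1, the myogenic determination factor, and MYMK, which drives myoblast fusion, were listed at 0 in srNMPs and at 96.6 ± 41.4 and 119 ± 33.3 FPKM in muscle (adjusted p = 2.38e-08 for each). Here and against neurons, the standard errors and p come from the groups with both lines. They do not measure variation between muscle cultures. CDH15 (6.93 ± 0.11) and the acetylcholine receptor subunit CHRNA1 (6.55 ± 0.24) rose. PAX3 and PAX7, factors of muscle precursors, had 2.01 ± 0.153 against 13.8 ± 12.3 and 9.21 ± 11.1 against 3.67 ± 4.07 FPKM (adjusted p = 0.165 and 0.219). Of 16 myogenic regulators 13 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 6.49e-10, and adjusted p = 0.0222 with an estimated correlation). Of 30 sarcomere genes 29 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.69e-27, and adjusted p = 0.00533 with an estimated correlation). MYLPF, a fast light chain (0.143 ± 0.0563 to 2043 ± 508 FPKM, log2 change 10.82 ± 0.32, adjusted p = 3.13e-07), and MYH3, the embryonic heavy chain (0.439 ± 0.133 to 1628 ± 458, log2 change 10.17 ± 0.18, adjusted p = 2.92e-08), were among them. ACTC1 rose from 7.21 ± 3.94 to 4717 ± 1046 FPKM (log2 change 9.31 ± 0.52, adjusted p = 1.22e-05). MYL1 was listed at 0 in srNMPs and at 1320 ± 248 in muscle (adjusted p = 4.99e-08).

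Of 7 cardiac genes TNNT2 (listed at 0 in srNMPs, 599 ± 212 FPKM in muscle, adjusted p = 2.38e-08) and RYR2 (2.21 ± 0.11) rose, also adjusted over the list alone (camera adjusted p = 0.0621). The heart factor NKX2-5 had 1.59 ± 0.00251 FPKM in muscle, which is HUES9 only, 4.08 and 3.66 in HUES9 srNMPs and 0.0428 and 0.0670 in H1 srNMPs. TNNT2 is also made by embryonic skeletal muscle. Collagen genes reached high levels. COL1A1 rose from 1.26 ± 0.635 to 6602 ± 2690 FPKM (log2 change 11.72 ± 0.37, adjusted p = 4.64e-07), COL1A2 to 4669 ± 1871 (10.66 ± 0.57) and COL3A1 to 2814 ± 286 (10.22 ± 0.60). LUM (8.21 ± 0.16) and the smooth muscle actin gene ACTA2 (4.07 ± 0.72) rose too. They were among 11 of 12 fibroblast and smooth muscle genes that rose, with 0 down, also adjusted over the list alone (camera adjusted p = 6.9e-10, but adjusted p = 0.0825 with an estimated correlation). Of 8 cartilage and tendon genes 5 rose and COL9A1 fell, also adjusted over the list alone (camera adjusted p = 0.000386, but adjusted p = 0.1 with an estimated correlation). The tendon genes TNMD (0.0228 ± 0.0456 to 382 ± 76.7 FPKM, log2 change 8.54 ± 0.17, adjusted p = 4.98e-08) and MKX (3.92 ± 0.09) and COL11A1 (3.52 ± 0.46) rose. SOX9 had 3.05 ± 0.208 against 2.45 ± 2.85. In the neural crest list SNAI2 (3.61 ± 0.47), ERBB3 (3.50 ± 0.50), ETS1 (3.04 ± 0.50) and NGFR rose and TFAP2B fell (4 and 1 of 12, also adjusted over the list alone; camera adjusted p = 0.123), with SOX10 at 0.718 ± 0.451 FPKM in muscle and, besides the HUES9 library of passage 8 (9.89), 0 to 0.241 in srNMPs.

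FGF17 (-6.95 ± 0.72), FGF8 (-6.48 ± 0.39), SOX2 (171 ± 28.8 to 3.27 ± 1.67 FPKM, log2 change -5.40 ± 0.19, adjusted p = 9.79e-07) and TBXT (-2.84 ± 0.53) were among 12 of 16 neuromesodermal genes that fell in muscle. FST, an activin inhibitor, rose, giving 1 up and 12 down, also adjusted over the list alone (camera adjusted p = 0.00746, but adjusted p = 0.337 with an estimated correlation). Of 18 proliferation genes 17 fell and 0 rose, 18 adjusted over the list alone (camera adjusted p = 4.88e-06, but adjusted p = 0.496 with an estimated correlation). The mitotic genes BUB1 (log2 change -3.47 ± 0.33, adjusted p = 0.000209), CCNB1 (-3.38 ± 0.30) and CCNB2 (-3.34 ± 0.30) fell, with MKI67 at 13.1 ± 1.58 against 46.6 ± 22.9 (adjusted p = 0.0684). Of 24 pan-neuronal genes 2 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.381). TUBB3 (-4.91 ± 0.33) and INA (-3.90 ± 0.32) fell and DCX rose (3.05 ± 3.74 to 60.1 ± 23.0 FPKM, 4.22 ± 0.85). LIN28A (-8.00 ± 0.78), IGDCC3 (-6.39 ± 0.13) and FGFBP3 (-6.06 ± 0.79) were among the largest decreases. In muscle against srNMPs 7034 genes were called, 2566 higher and 4468 lower (36.5% higher), and the median change of all genes was -0.22. At equal totals 48.4% were higher (3013 and 3215) with a median of -0.02. With only the 6 libraries of this contrast 1665 were called, 1177 higher and 488 lower (70.7% higher). Both muscle libraries are from HUES9, so the comparison rests on the cell line term fitted to the other groups.

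Muscle was set against neurons to separate the fates. MYOG (log2 change 8.48 ± 0.11, adjusted p = 2.55e-08), ACTC1 (3.47 ± 1.49 to 4717 ± 1046 FPKM, log2 change 10.11 ± 0.52, adjusted p = 8.03e-06), MYLPF (9.95 ± 0.32) and MYL1 (9.70 ± 0.21) were higher in muscle. Of 16 myogenic regulators 13 were higher and LBX1, shared with dorsal interneurons, was lower (-2.86 ± 0.80, camera adjusted p = 1.7e-12, and adjusted p = 0.0133 with an estimated correlation). Sarcomere genes were higher in 29 of 30 (camera adjusted p = 2.71e-33, and adjusted p = 0.00334 with an estimated correlation). All 12 fibroblast and smooth muscle genes were higher (camera adjusted p = 1.31e-12, and adjusted p = 0.0472 with an estimated correlation), led by COL1A1 (10.54 ± 0.37), COL3A1 (10.10 ± 0.60), COL1A2 (9.97 ± 0.57) and ACTA2 (6.14 ± 0.72). STMN2 (1.61 ± 0.431 FPKM in muscle, 623 ± 116 in neurons, log2 change -7.98 ± 1.13, adjusted p = 0.00126), INA (-7.39 ± 0.32) and TUBB3 (-6.36 ± 0.33) were among 21 of 24 pan-neuronal genes lower in muscle (camera adjusted p = 2.82e-07, but adjusted p = 0.367 with an estimated correlation), as were the vesicle genes NSG1 (-7.33 ± 0.59) and NSG2 (-7.20 ± 0.65). SST (-5.54 ± 0.98) and SLC17A6 (-3.76 ± 0.33) were among 9 of 13 neurotransmitter genes lower (camera adjusted p = 0.00915, but adjusted p = 0.407 with an estimated correlation). These counts were the same adjusted over the list alone.

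SNAI2 (5.23 ± 0.47) and ERBB3 (4.97 ± 0.50) were among 3 of 12 neural crest genes higher in muscle and TFAP2B was lower (camera adjusted p = 0.186), with SOX10 at 0.718 ± 0.451 against 1.63 ± 2.21. CD44 (3.28 ± 0.14) and GJA1 were the 2 of 12 central glia genes higher and SOX9 (-3.87 ± 0.60) was among 4 lower (camera adjusted p = 0.885), with GFAP at 1.89 ± 1.51 against 6.32 ± 6.29. HOXB9 had 3.89 ± 0.136 FPKM in muscle and 428 ± 338 in neurons (log2 change -5.90 ± 0.34, adjusted p = 1.38e-05). HOXB8 (-5.48 ± 0.36) and HOXA6 (-2.35 ± 0.70) were also among 9 of 12 paralogs 6 to 9 lower in muscle, 10 adjusted over the list alone (camera adjusted p = 0.0164, but adjusted p = 0.494 with an estimated correlation). HOXD11 (21.0 ± 0.0365 FPKM against 0.0645 ± 0.0650, log2 change 4.34 ± 0.09, adjusted p = 5.8e-08) and HOXD10 (3.45 ± 0.72) were among 8 of 10 paralogs 10 to 13 higher, with 0 lower (camera adjusted p = 2.35e-08, but adjusted p = 0.0902 with an estimated correlation). HOXA10 and HOXC10 had 13.6 ± 0.266 and 20.2 ± 0.572 against 10.7 ± 12.7 and 18.8 ± 24.4. In the HUES9 neurons alone HOXA10 stood at 25.5 (dorsal) and 17.1 FPKM (ventral) and HOXC10 at 51.6 and 23.2, and muscle is HUES9 only. Except for paralogs 6 to 9, these counts too were the same adjusted over the list alone. In all, 6572 genes were called, 2060 higher and 4512 lower in muscle (31.3% higher), with a median change of all genes of -0.34. With quantile normalization 46.2% were higher (2742 and 3195) and the median was -0.10. The calls of LBX1 (smaller pseudocount, equal totals) and HOXD10 (smaller pseudocount) ended under those settings.

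Day 50 muscle was set beside day 40 without a test, since each day has 1 library. Muscle genes were higher at day 50 and matrix genes lower. MYOG went from 312 FPKM at day 40 to 539 at day 50, MYOD1 from 67.3 to 126, MYH3 from 1304 to 1952, the perinatal heavy chain MYH8 from 153 to 365 and the creatine kinase CKM from 118 to 296. COL1A1 went from 8504 to 4700 FPKM, COL1A2 from 5992 to 3346, the cartilage gene ACAN from 18.5 to 3.28 and TNMD from 437 to 328. PAX7 went from 1.36 to 17.1 FPKM. The median log2 difference was 0.56 for myogenic regulators (12 of 16 higher), 0.58 for sarcomere genes (30 of 30 higher) and 0.52 for neural crest genes (9 of 12 higher), each at percentile 100 of 10000 random lists. It was -0.54 for fibroblast and smooth muscle genes (0 of 12 higher, percentile 0) and -0.45 for cartilage and tendon genes (3 of 8 higher, percentile 0.01). Cardiac (percentile 48.9), neuromesodermal (51.2), proliferation (13.1) and pan-neuronal genes (12.5) lay inside the random range. Genes of a list can vary together and each day has 1 library, so these percentiles describe the 2 libraries and test no difference of days. Across genes the days had a Spearman's rho of 0.982, with 102 genes at least 2-fold higher and 118 at least 2-fold lower at day 50.

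HUES9 was compared with H1 within the 6 groups that hold both lines. limma called 0 genes (smallest adjusted p = 0.883), with 512 at an unadjusted p under 0.05. Of the 7 lists set for this comparison, neural progenitor (camera adjusted p = 0.00278), HOX paralogs 1 to 5 (0.00278) and 10 to 13 (0.00787) and proliferation (0.000133) were higher in HUES9 as lists, with 0 members called, also adjusted over the list alone. Each had adjusted p = 0.724 with an estimated correlation. For proliferation 1 pair stood apart, with mean log2 levels of 5.57 in HUES9 and 4.10 in H1 dorsal neurons, against 6.11 and 6.11 in RABC, 6.20 and 6.27 in RASS, 6.23 and 6.07 at passage 25, 6.03 and 6.03 at passage 8 and 3.64 and 3.49 in ventral neurons. Mean log2 levels of neural progenitor genes differed most at passage 25 (4.486 in HUES9, 3.001 in H1) and in dorsal neurons (4.502 and 3.77). They were lower in HUES9 at passage 8 (3.103 and 3.459). They stood at 4.397 and 4.351 in RABC, 5.075 and 4.746 in RASS and 3.696 and 3.499 in ventral neurons. HOX paralogs 1 to 5 were lower in HUES9 in RABC alone (3.96 and 4.372). The list tests were not repeated with the RASS lines exchanged. The fit without group means also held the HUES9-only ESC and muscle libraries, so line and state were mixed in it. In that fit HOX paralogs 1 to 5 (camera adjusted p = 0.145) and neural progenitor genes (0.516) turned direction and proliferation no longer passed (0.906). In the main fit 3 genes of paralogs 1 to 5 and 2 of paralogs 10 to 13 stood at an unadjusted p under 0.05. So did 2 of fibroblast and smooth muscle, 1 of neural crest and 0 of the other 3 lists. Fibroblast and smooth muscle (0.0863, and 0.0303 at equal totals), HOX paralogs 6 to 9 (0.408) and neural crest (0.57) lists had 0 called members, also adjusted over the list alone. In the fit without group means fibroblast and smooth muscle turned direction (camera adjusted p = 0.000109) and neural crest passed (0.0313). Mean log2 levels of the fibroblast list were 7.66 and 7.04 in the HUES9-only muscle libraries and 0.622 to 1.88 elsewhere. That turn therefore cannot be told apart from a difference of muscle. The HUES9 minus H1 differences of the RASS pair ran opposite to those of the other groups. Their correlations across genes with the other 5 pairs were -0.51 to -0.127, while those among the other 5 pairs were 0.0406 to 0.359. Without RASS_7D replicate 1, 66 genes were called between the lines, without RASS_7D replicate 2 62, without both 65 and with their lines exchanged 147.

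The change from srNMPs had Pearson's r across genes between the lines of 0.701 for progenitors and 0.866 for neurons. Ventral against dorsal neurons gave 0.571, and RASS against RABC 0.248, or 0.67 with the lines of the RASS libraries exchanged. Genes are not independent replicates, so no p is given. The test of a difference between lines called 0 genes for progenitors (309 at an unadjusted p under 0.05, smallest adjusted p = 0.559) and 0 for neurons (625, smallest adjusted p = 0.196) in limma. On simulated data the test for neurons recovered 94% of differences of 3 on the log2 scale, placed only in genes of higher mean level. Dorsal and ventral neurons, and the passages, stood as replicates in this test, and their real differences add to its spread. The simulated groups of a state did not differ, so the 94% leaves out that spread.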

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

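The tests of line labels and of carried-over RNA given here were chosen only after the results were seen. List means in this section cover the tested members, while mean log2 levels of lists elsewhere in the text cover all members in the table. Of 102 pairs of a state and a measure, 7 held a library far from the other 3, and chance alone gives about 1 in 20 such groups.

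The line differences of the RASS pair ran opposite to those of the other 5 pairs (correlations of -0.51 to -0.127). Of 23 genes on in all 5 other libraries of one line and off in all 5 of the other, 22 (95.7%) stood on the side of the opposite line in both RASS libraries, and 0 stood as labelled. PEG3 was at 10.7 to 135 FPKM in the other HUES9 libraries of these groups and at most 0.0376 in those of H1, with 22.4 in the library labelled H1 RASS_7D and 0.0132 in the library labelled HUES9 RASS_7D, and CAT showed the mirror image (0.0124 and 16.1). A single library from the other line would put these genes on the same side in both RASS libraries, and a response to RASS that runs opposite ways in the lines would leave genes that mark a line in every other group as labelled, yet 0% did either. Exchanging the RASS lines was the 1 of 32 ways to assign lines within the groups that gave calls between lines in limma fitted to these 12 libraries (142, against 0 for the labels as given, with 506 at an unadjusted p under 0.05), and these values are consistent with exchanged lines in the RASS pair.

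The HUES9 library of srNMP passage 25 stood apart in mean log2 level of ventral neural progenitor genes (1.16, others 0.0445 to 0.143) and of ventral interneuron genes (1.45, others 0.613 to 0.722). In all, 14 neural genes were raised there, among them PAX6 at 24.5 FPKM against at most 0.32 in the other srNMP libraries, NKX6-1 at 22.0 against at most 0.94 and STMN2 at 72.0 against at most 13.3. RNA carried over from another library of the series would bring the abundant genes of that library too, and for each of 9 donor libraries the share that the neural genes need was at least 11.5 times the share that those abundant genes reached (lowest for the library labelled HUES9 RASS_7D, 35.6% needed and 3.1% reached). Both RABC libraries had fewer than 5 such genes, but with NKX6-1 at 0.00814 and 0.590 FPKM they could not have brought the level seen of that gene. Cells that had begun to differentiate in this culture are a candidate explanation that 1 library (HUES9 at passage 25) leaves open.

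The mean of dorsal interneuron genes in the H1 library of srNMP passage 8 was 0.811, against 0.514 to 0.561 in the other srNMP libraries. Cartilage and tendon genes had a mean of 1.58 in the library labelled HUES9 RASS_7D, against 1.71 to 1.73 in the other progenitor libraries. BMP targets had a mean of 2.62 in HUES9 dorsal neurons, against 1.98 to 2.04 in the other neuron libraries. H1 ventral neurons had a mean of 4.11 for cell stress genes (others 3 to 3.17) and an FPKM total of 305000 (others 290000 to 292000). Of 23 list and comparison pairs set between lines, 2 moved opposite ways by a median of at least 0.5 in each line, both between passages 25 and 8 with 1 library per line at each: HOX paralogs 6 to 9 by a median of 0.652 in H1 and -1.19 in HUES9, and neural progenitor genes by -0.579 in H1 and 1.03 in HUES9. These differences between lines were not tested.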

How the results depend on the processing

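The fits with exchanged RASS lines, the fits without both RASS libraries and the list tests at equal totals were chosen only after results were seen. Fitting only the libraries of a contrast left 365 calls for srNMPs against ESCs, 1665 for muscle against srNMPs, and 0 each for progenitors, for RASS against RABC and for ventral against dorsal neurons. The share higher was 6.03% for srNMPs against ESCs and 70.7% for muscle against srNMPs there, against 52.4% and 36.5%. That setting has fewer libraries and residual degrees of freedom by construction. A minimum of 2-fold left 3481 calls in neurons, 4471 in muscle against srNMPs and 4020 in muscle against neurons. With muscle days as 1 group the muscle counts were 7468 and 7075, and with a pseudocount of 0.1, equal totals or quantile normalization each count of calls stayed within 1.5 times of its value. Without the filter on low values 191 genes were called in progenitors and 48 in RASS against RABC, and without the replicate block 772 in progenitors. With exchanged RASS lines the counts were 875 in progenitors, 113 in RASS against RABC and 147 in HUES9 against H1, and without both RASS libraries 25 in progenitors and 65 in HUES9 against H1. Leaving out 1 library at a time gave 1503 (without srNMP_P25 replicate 2) to 2705 calls for srNMPs against ESCs and 1 to 5 between passages. It gave 45 (without RABC_7D replicate 1) to 2281 (without srNMP_P8 replicate 1) in progenitors and 8 (without RABC_7D replicate 1) to 73 in RASS against RABC, with 32 without RABC_7D replicate 2. The share higher in RASS against RABC turned to 31.2% without RABC_7D replicate 2, and in ventral against dorsal neurons to 44.1% and 46.7% without dorsal_neurons replicates 1 and 2. Leaving out 1 library gave 5400 to 7677 in neurons, 137 (without dorsal_neurons replicate 2) to 412 (without ventral_neurons replicate 2) in ventral against dorsal neurons, 5084 to 7497 and 4541 to 6205 for muscle against srNMPs and neurons, and 0 to 66 (without RASS_7D replicate 1) in HUES9 against H1. A library left alone in its group is assumed to vary like the other groups, and no fit without the ESC library could be made. In RASS against RABC such fits called partly other genes than the main fit, also where the count was the same. Apart from the settings of fewer libraries, the cause was not tested.

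The correlation between lines moved with a pseudocount of 0.1 to 0.69 in progenitors, 0.195 in RASS against RABC, 0.858 in neurons and 0.587 in ventral against dorsal neurons. In ventral against dorsal neurons it was 0.565 without the filter and 0.561 with quantile normalization. With exchanged RASS lines it was 0.747 in progenitors and 0.67 in RASS against RABC. In HUES9 against H1 the setting without the replicate block dropped the group means and took in the HUES9-only ESC and muscle libraries. Line and state are mixed there. In it 3 list tests turned direction: HOX paralogs 1 to 5 (camera adjusted p = 0.145), neural progenitor (0.516) and fibroblast and smooth muscle (0.000109). In that comparison neural crest passed (0.0313) and proliferation no longer did (0.906). The direction of lists not called was not counted. Without the replicate block the other 69 of 74 list tests kept their side of the threshold, and those called kept direction. With quantile normalization 73 of 74 did, and at equal totals 70, where neural crest in progenitors (0.00605) and fibroblast and smooth muscle in HUES9 against H1 (0.0303) passed and neurotransmitter (0.0527) and central glia genes (0.0762) in neurons no longer did. With an estimated correlation 8 of 40 called lists stayed called. Of 193 calls of named genes 15 ended with a pseudocount of 0.1, 6 at equal totals, 6 without the replicate block and 4 with quantile normalization, and 0 reversed, while 7, 3, 5 and 1 other named genes became called. The cause of these changes was not tested. FPKM hold no counts, so what depth limits could be estimated only from the smallest values.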

Other observations

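The tests of other splits below, and the genes named singly in this part, were chosen after the values were seen. Forebrain and midbrain genes separated the ESC library from srNMPs. SIX6, an eye and forebrain factor, stood at 33.7 FPKM in the ESC library and was listed at 0 in all 4 srNMP libraries (adjusted p = 8.2e-08), and the forebrain genes SIX3 (-2.90 ± 0.08) and OTX2 (-2.68 ± 0.08) fell, while the hindbrain and midbrain border genes EN2 (5.88 ± 1.46) and PAX2 (3.93 ± 0.89) rose. Of 8 genes in that list 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.00813, but adjusted p = 0.222 with an estimated correlation). Surface ectoderm genes had 4 of 7 lower in srNMPs, 5 adjusted over the list alone (camera adjusted p = 0.000235, but adjusted p = 0.222 with an estimated correlation), with the epithelial keratin genes KRT8 and KRT18 at 295 and 397 FPKM in the ESC library. Some mesoderm genes outside the muscle lists rose in muscle. Of 15 paraxial mesoderm and somite genes 8 rose and 1 fell against srNMPs, 9 and 1 adjusted over the list alone (camera adjusted p = 7.23e-05, but adjusted p = 0.0854 with an estimated correlation). MEOX2, a somite factor, stood at 53.6 FPKM at day 40 and 27.5 at day 50, and PAX9, listed at 0 in srNMPs, at 9.22 and 6.97. Of 6 endothelial and blood genes CD34, TEK and ERG rose (3, also adjusted over the list alone, camera adjusted p = 0.0194, but adjusted p = 0.158 with an estimated correlation), with CD34 at 8.84 and 8.89 FPKM. TEK had 2.69 and 2.77 and ERG 2.55 and 1.12 FPKM at day 40 and day 50. Endothelial genes did not all rise, and KDR, PECAM1 and TIE1 stood at 0.0794 FPKM or less in both muscle libraries. HOX paralogs 10 to 13 had 8 of 10 higher in muscle than in srNMPs, also adjusted over the list alone (camera adjusted p = 2.39e-07, but adjusted p = 0.116 with an estimated correlation), and BMP targets 6 of 12, also adjusted over the list alone (camera adjusted p = 0.0345, but adjusted p = 0.496 with an estimated correlation). In progenitors 4 of 7 hedgehog targets rose against srNMPs, 5 up and 1 down adjusted over the list alone (camera adjusted p = 0.000732, but adjusted p = 0.301 with an estimated correlation). The mean log2 level of this list was 3.35 and 3.68 in the RASS libraries and 1.14 and 1.15 in those of RABC. Among srNMPs it was 1.30 in HUES9 at passage 25, above both RABC libraries. The other srNMP libraries had 0.732 to 0.869, below both RABC libraries. In ventral against dorsal neurons limma called 0 of 13 cell stress genes, 0 also adjusted over the list alone (4 at an unadjusted p under 0.05; camera adjusted p = 0.0363, but adjusted p = 0.438 with an estimated correlation).

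Several developmental regulators separated the libraries by line. HOXC10, a lumbar-level HOX gene, was at 0 to 0.661 FPKM in the H1 libraries other than RASS and at 8.01 to 51.6 in the HUES9 libraries of the same groups, with 13.5 in the library labelled H1 RASS_7D and 0.0151 in the library labelled HUES9 RASS_7D. TBX1, TLX1 and BARX1, developmental transcription factors, were each at least at 1 FPKM in those HUES9 libraries and under 0.5 in those of H1. The H1 library of srNMP passage 8 had CDX2 at 0.00615, HOXC9 at 0.0565 and HOXC8 at 0.218 FPKM, where the H1 library of passage 25 had 11.5, 9.84 and 7.93. DBX1, a factor of intermediate spinal progenitors, reached 66.0 FPKM in the HUES9 library of passage 25 and 60.5 in the library labelled HUES9 RASS_7D, and at most 0.388 elsewhere. In ventral neurons the lines had different levels of interneuron genes. H1 had the interneuron gene SOX14 at 27.1 FPKM, against 2.47 in HUES9, while HUES9 had the floor plate signal SHH at 9.53, NKX2-2 at 73.7 and the V3 interneuron factor SIM1 at 4.83, against 1.47, 3.03 and 0.330 in H1. With 1 library per line these differences were not tested.

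Other splits of the libraries were set beside the real ones. Fitted to their 8 libraries as 2 groups with the line term, progenitors against srNMPs gave 194 calls, the highest of 34 splits fitted out of 35 (1 split as large), with 44 the highest of the others. The split with 44 calls put the H1 libraries of RABC and srNMPs with the library labelled HUES9 RASS_7D. With the RASS lines exchanged it would be the split by line. The line term and line balance of these splits follow the labels as given. In neurons against srNMPs 1 of 34 splits, the real one, gave as many calls (6424), and the highest of the others gave 0. The lines pair the libraries, and in each comparison 18 of these splits hold as many libraries of each line per side as the real one, with 0 the highest of the others among them. These 18 are too few for a share under 0.05. For HUES9 against H1 limma called 0 genes (506 at an unadjusted p under 0.05 in the fit of the 12 libraries), so each of 100 drawn of 462 splits had to give as many, and they say nothing about chance. The highest of the others gave 63 calls.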
